A study of Mus musculus with 18 samples.

How the data were processed

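RNA of mouse embryonic stem cells (ESCs) was measured on 18 Affymetrix arrays, 1 array per sample. The samples were male 129SV EBRTcH3 ESCs in serum with LIF or in 2i medium, derivatives overexpressing wild-type or T58A c-Myc, Max-null ESCs and Max-null ESCs overexpressing p110 alpha. LY294002 (spelled LY4294002 in the design), an inhibitor of PI3K, was present until day 2 or day 5, and doxycycline (Dox), which ablates Max expression in the Max-null lines per the labels, until day 4 or day 6, with the day not given for the p110 alpha line. Per the labels, total RNA was extracted with TRIzol and hybridised as biotin-labelled cRNA. The deposited table holds log2 probe set values that the authors computed by RMA with the affy package, whose versions and settings were not given. The 4 arrays of parental serum replicate 1 and of parental 2i ESCs had medians of 5.03 to 5.05 and the other 14 arrays 5.31 to 5.52, so they appear to come from separate RMA runs. No label states the runs, and every RMA run named below is this inferred grouping. No number of reads or cells stands behind an array value, and the number of arrays limits the precision.

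The table held 45101 probe sets, of which 64 were controls, 34958 named 1 gene, 932 named several genes and 9211 named none in the platform annotation. Of the probe sets for 1 gene, 34754 were matched to a reference gene by gene identifier. Each of 18194 genes was given the probe set with the highest mean over the 18 arrays, a choice that mattered for the 9012 genes with several. Genes were tested where at least 2 samples of the fit, or 1 sample of an untested pair, lay above a log2 level of 4.64, the 40th percentile of the table.

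Treated samples were paired with the reference sample that their description names. The change with LY294002 at day 5 was tested in 8 serum samples with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with the pair as a block. This fit gave coefficients for the 2 parental pairs, for the 2 c-Myc lines and for their difference, with 2 residual degrees of freedom. As a check of the pairing, the difference between the 2 parental pairs in their untreated samples correlated over genes with that in their day 5 samples at r = 0.564, a value that includes any offset between the RMA runs. Between the c-Myc lines the same r was 0.113. Day 2 was tested in the 9 samples of parental replicate 2 and both c-Myc lines with line as a block and 4 residual degrees of freedom. Dox was tested in the 5 samples of the Max-null lines with line as a block, both Max-null days counted as Dox, and 2 residual degrees of freedom. Its coefficient is not an even average of the lines, since the Max-null line has 2 Dox samples and the p110 alpha line 1. The day 5 coefficient of the 9-sample fit was added after the data were seen, because these samples appear to share 1 RMA run. All p-values are 2-sided and Benjamini-Hochberg adjusted over the genes of a comparison, with a threshold of 0.05, and measure the spread between these samples, since separate cultures were not stated. Comparisons with 1 sample per group were not tested. Their genes were counted where they differed at least 2-fold, which is 1 on the log2 scale.

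The 25 gene lists covered naive pluripotency, the formative and primed epiblast, primitive streak and mesendoderm, primitive and visceral endoderm, trophoblast, neuroectoderm, 2-cell-like cells, germ cells and meiosis, and fibroblasts as feeder cells. Others held FOXO and PI3K-feedback targets, cholesterol and fatty acid synthesis, glycolysis, ribosome biogenesis with Myc targets, DNA replication and mitosis, and p53 targets with CDK inhibitors. The rest held the ATF4 and amino acid response, the ERK response, Wnt targets, lysosome and autophagy, the interferon response, imprinted genes, DNA methylation machinery, the Myc-Max network, PI3K pathway components, and heat shock with oxidative stress. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 25 lists. The second setting also takes the residual degrees of freedom of the fit, 2 or 4. A list that fails there may thus fail for want of samples and not for correlated genes. In untested pairs a list's median was placed among 10000 random lists of equal size matched on mean level.

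The lists, comparisons, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 8 largest rises and the 8 largest falls that passed and had the same direction in every pair, or the 5 smallest p-values in each direction where fewer than 5 passed. In an untested pair it takes the 6 largest differences each way, and for each list described the 4 members with the smallest p or the largest difference. Any further gene was chosen after its values were seen. Myc, Mycn, Max and Pik3ca were looked up in every sample. Alternatives changed the level filter, the scaling of the arrays, the probe set per gene, the eBayes prior, the thresholds, the block and the samples.

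The fits were tested on simulated data in which 200 of 13101 to 13666 genes had been changed. For 2-fold changes the share recovered was 24% in the parental and 32% in the c-Myc comparison, 86% at day 2 and 87% at day 5 over 3 lines. For 4-fold changes it was 71%, 69%, 97% and 98%. Each simulated gene had the same spread in every pair. In the data the day 5 changes correlated at r = 0.428 between the parental pairs and 0.917 between the c-Myc lines. The real shares may thus differ from the simulated ones. In the difference between c-Myc and parental lines and in the Dox fit 0% was recovered at either size, so a count of 0 there says little. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.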

Results

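The series compared genome-wide RNA levels of mouse ESCs on 18 arrays. In serum, parental ESCs had 2 untreated samples, 2 samples at day 5 of LY294002 and 1 at day 2. ESCs overexpressing wild-type c-Myc and those overexpressing c-Myc T58A each had 1 untreated, 1 day 2 and 1 day 5 sample. Parental ESCs in 2i, a medium with inhibitors of MEK and GSK3, had 1 untreated and 1 day 5 sample. Max-null ESCs, whose Max expression is ablated by Dox, had 1 untreated, 1 day 4 and 1 day 6 sample. Max-null ESCs overexpressing p110 alpha, the catalytic subunit of PI3K, had 1 untreated and 1 Dox sample. Changes are log2 differences, given with the standard error where a test was run, and single samples carry no error. The number of arrays limits the precision. The description of the untreated T58A sample calls the treated samples it serves N-Myc overexpressing, so their construct rests on their other labels.

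The levels of the manipulated genes came first. Myc, the gene for c-Myc, read 7.51 and 6.99 in untreated wild-type and T58A c-Myc ESCs and 9.30 and 7.43 in the untreated parental replicates. With LY294002 at day 5, Myc was at 10.26 and 9.60 in the parental replicates, 9.60 in wild-type and 9.55 in T58A c-Myc ESCs, and in 2i it went from 6.05 to 6.97. Mycn read 10.07 and 9.33 in the untreated c-Myc lines and 10.96 and 11.33 in the untreated parental replicates. Max, the obligate partner of c-Myc, lay between 8.17 and 8.71 in all parental and c-Myc arrays. It read 7.09, 6.89 and 7.18 in Max-null ESCs untreated and at Dox days 4 and 6, and 6.70 and 6.33 in p110 alpha Max-null ESCs without and with Dox. Pik3ca, the gene for p110 alpha, read 8.82 in untreated p110 alpha Max-null and 8.50 in untreated Max-null ESCs. Myc and Max had 1 probe set each, and whether the probe sets cover the introduced cDNAs or the ablated part of Max is not stated, so these values check neither overexpression nor ablation.

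The first question was what LY294002 does to parental ESCs in serum by day 5. Slc40a1, the iron exporter ferroportin, rose 11.1-fold (3.47 ± 0.26, SE, n = 2 pairs; adjusted p = 0.044), and the kinase gene Pim2 rose 9.47-fold (3.24 ± 0.22). Also raised were Hs6st2, which sulfates heparan sulfate, by 2.84, the transcription factor genes Sox11 by 2.79 and Sox3 by 1.52, the integrin gene Itga1 by 2.33, the ephrin gene Efnb2 by 2.18 and the imprinted gene Peg10 by 2.17. The glycosyltransferase gene B4galnt2 fell by 3.43 and the protease inhibitor gene Serpinb6c fell by 3.14. Also lowered were Niban1 (-2.81), the adhesion receptor gene Adgrd1 (-2.77), Dleu7 (-2.69), Mapt, which encodes tau (-2.40), the Hedgehog effector Gli1 (-2.39) and the phospholipase gene Pla1a (-2.37). In limma's test of 13405 genes 71 passed, 15 higher and 56 lower, each at least 2-fold and in the same direction in both parental pairs. At an unadjusted p under 0.05 there were 2927 genes, 1418 higher and 1509 lower.

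Genes of the formative and primed epiblast, the state that follows naive pluripotency, had the largest median change among the lists in parental ESCs at day 5. Of 12 tested, 2 rose over all genes, Pim2 and Sox3, and 10 did not pass, while 9 rose adjusted over the list alone. The DNA methyltransferase gene Dnmt3b was higher by 1.23 and 1.57 in the 2 pairs and the cadherin gene Cdh2 by 1.79 and 1.22, with adjusted p-values of 0.057 and 0.059 over all genes. The list had a median change of 1.45 (camera adjusted p = 3.7e-07; adjusted p = 0.777 with an estimated correlation). Of 19 naive pluripotency genes none passed over all genes, and 13 fell and 1 rose adjusted over the list alone. Tcl1, a coactivator of Akt, differed by -1.61 and -2.47 in the pairs (mean -2.04, adjusted p = 0.061), Prdm14 had a mean change of -1.16, Fbxo15 of -1.71 and Nr5a2 of -1.39, while Pou5f1, the gene for Oct4, had an adjusted p of 0.936. The naive list had a median of -0.66 (camera adjusted p = 5.44e-07; adjusted p = 0.777 with an estimated correlation).

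Among 23 genes of the ATF4 and amino acid response, which supplies amino acids under stress, 0 passed over all genes or adjusted over the list alone, yet all had fitted changes below 0. Its median was -0.66 (camera adjusted p = 1.32e-07; adjusted p = 0.777 with an estimated correlation). The 16 lysosome and autophagy genes had a median of -0.33 with 0 passing either way (camera adjusted p = 0.004; adjusted p = 0.777 with an estimated correlation). Of 27 germ cell genes, 1 fell over all genes, the synaptonemal complex gene Sycp3 (-1.40, adjusted p = 0.044), and 7 fell and 1 rose adjusted over the list alone. The germ cell median was -0.26 (camera adjusted p = 0.0138; adjusted p = 0.777 with an estimated correlation). Of 16 ERK response genes none passed over all genes and 6 rose adjusted over the list alone, among them Junb and Egr1 with mean changes of 1.09 and 0.98 (median 0.51, camera adjusted p = 0.0307; adjusted p = 0.777 with an estimated correlation). The 33 genes of ribosome biogenesis and Myc targets had a median of 0.19 with 0 passing either way (camera adjusted p = 0.0157; adjusted p = 0.777 with an estimated correlation). The other 18 lists did not pass, with camera adjusted p-values of 0.121 to 0.953.

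**Figure D1:**
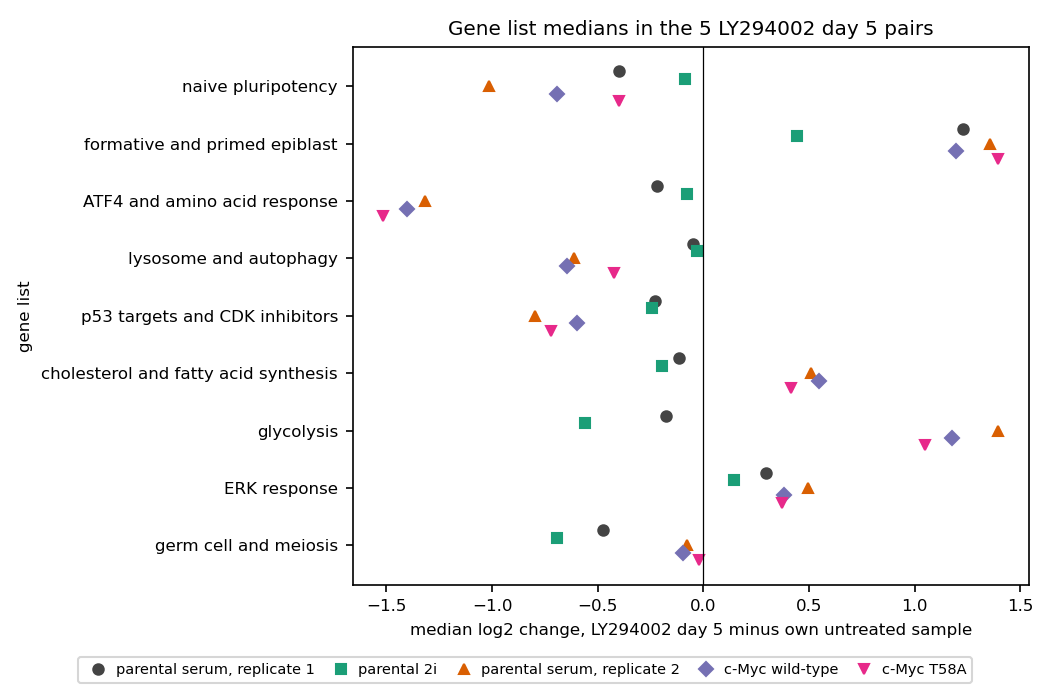
Median log2 change of 9 gene lists (vertical axis) in each of the 5 pairs of a sample at LY294002 day 5 and its own untreated sample (points, 1 array per sample). The formative list lay between 0.44 and 1.40 in all 5 pairs, while glycolysis ran from -0.56 in 2i to 1.39 in parental replicate 2.

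The parental result depended on the samples that set the spread. The count was 0 without a replicate block, 0 in the 4 parental samples alone with or without a block, and 0 without the wild-type or without the T58A pair. It was 4711 without parental pair 1, 1205 without parental pair 2, and 455 at a threshold of 0.1. Single pairs showed the same unevenness: 469 genes differed at least 2-fold in replicate 1, 83 higher and 386 lower, against 1340 in replicate 2, 809 higher and 531 lower. The changes of the 2 pairs correlated over genes at r = 0.428, 1 of 13 such correlations computed, where genes are not independent replicates. List medians of replicates 1 and 2 were -0.22 and -1.32 for ATF4, -0.05 and -0.61 for lysosome, -0.40 and -1.02 for naive, -0.47 and -0.08 for germ cell, 0.30 and 0.49 for ERK response, 0.181 and 0.184 for ribosome biogenesis, and 1.23 and 1.35 for formative genes. Glycolysis genes went apart as well: the mitophagy gene Bnip3 differed by -0.50 in replicate 1 and by 3.59 in replicate 2. The glycolysis list had a median of -0.18 in replicate 1, below all but 0.3% of random lists, and of 1.39 in replicate 2. Beside that difference, untreated Bnip3 stood at 11.54 in replicate 1 and 8.52 in replicate 2, and the replicates appear to belong to separate RMA runs.

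In ESCs overexpressing c-Myc the question was what LY294002 does by day 5 when c-Myc is supplied. Slc40a1 rose 18.8-fold (4.24 ± 0.26, n = 2 lines; adjusted p = 0.031), Hs6st2 rose by 3.79, Pim2 by 3.25, the potassium channel gene Kcnk1 by 2.85, the Wnt effector Lef1 by 2.66, Atp10a by 2.64, Tmem54 by 2.56 and Itga1 by 2.44. The cation channel gene Trpm1 fell 19.4-fold, a change of -4.28 ± 0.19 (adjusted p = 0.031). Further falls were those of B4galnt2 (-3.80), Serpinb6c (-3.47), Zmat4 (-3.30), Ripply3 (-3.00), Cth, which makes cysteine from cystathionine (-2.98), Lrrc31 (-2.89) and the adenylate kinase gene Ak7 (-2.81). Endogenous or introduced, the Myc signal rose by 2.33 (adjusted p = 0.049) and Mycn rose by 2.43 (adjusted p = 0.031). Of 13405 genes 351 passed, 146 higher and 205 lower, 273 of them at least 2-fold, and each had the same direction in both lines. With each array centred on its median the split was 189 higher and 186 lower.

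Of 12 formative genes tested in the c-Myc lines, 5 rose over all genes and 7 did not pass, with 10 rising adjusted over the list alone. They included Dnmt3b (1.81, adjusted p = 0.036), Dnmt3a (1.70, adjusted p = 0.044) and Lef1. The list's median was 1.12 (camera adjusted p = 1.01e-06; adjusted p = 0.700 with an estimated correlation). Of 19 naive genes, 1 fell over all genes, Tcl1 (-2.26, adjusted p = 0.04), and 18 did not pass, among them Klf5 and Tfcp2l1 with mean changes of -1.20 and -1.08. Adjusted over the list alone, 9 fell and 1 rose (median -0.55, camera adjusted p = 0.000239; adjusted p = 0.700 with an estimated correlation). Of 23 ATF4 genes, 3 fell over all genes and 22 fell adjusted over the list alone. The 3 were Atf3, itself a stress-induced transcription factor (adjusted p = 0.04), Ddit4, an inhibitor of mTORC1 (-1.52), and the proline synthesis gene Aldh18a1 (-1.53), and the median was -1.47 (camera adjusted p = 8.38e-13; adjusted p = 0.700 with an estimated correlation).

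Of 17 p53 targets and CDK inhibitors in the c-Myc lines, 3 fell and 1 rose over all genes, and 9 fell and 3 rose adjusted over the list alone. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, fell by 1.66, Plk2 and Btg2 fell too (-2.07 and -1.16), and the pro-apoptotic Pmaip1 rose by 1.49. The p53 list had a median of -0.66 (camera adjusted p = 0.0153; adjusted p = 0.700 with an estimated correlation). Cholesterol and fatty acid synthesis had 0 of 27 passing over all genes and 7 rising adjusted over the list alone, with means of 1.00 for Sqle and 1.25 for Fdps (median 0.45, camera adjusted p = 5.8e-05; adjusted p = 0.754 with an estimated correlation). Of 16 lysosome genes, Hexa fell over all genes (-1.55) and 2 fell adjusted over the list alone (median -0.54, camera adjusted p = 0.000208; adjusted p = 0.700 with an estimated correlation). The 19 glycolysis genes had a median of 1.11 with 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.0041; adjusted p = 0.816 with an estimated correlation). Of 16 ERK response genes, Myc rose over all genes and 3 rose adjusted over the list alone (median 0.41, camera adjusted p = 0.0476; adjusted p = 0.700 with an estimated correlation). The count of 351 was 0 without the wild-type or without the T58A line, 44 without a replicate block, 5503 without parental pair 1 and 5527 without parental pair 2. It was 1815 at a threshold of 0.1, 533 with the level filter at the 60th percentile and 536 with a trended, robust prior.

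Whether c-Myc overexpression altered the day 5 change was tested as the difference between the c-Myc lines and parental ESCs. The genes with the smallest p-values in each direction did not pass: the prostaglandin receptor gene Ptger2 lay higher by 1.75 ± 0.16 in the c-Myc lines (changes of 1.59 and 1.70 against -0.19 and -0.01), and Mycn by 1.82. Pof1b, Tnfsf11 and Nudt12 lay higher by 1.33, 1.29 and 1.25. Ankrd33b lay at -1.51, the histone gene H2aw at -1.38, Trpm1 at -1.94, Ripply3 at -1.87 and Sox3 at -1.03. Untreated Mycn read 10.07 and 9.33 in the c-Myc lines against 10.96 and 11.33 in the parental replicates. At day 5 it read 12.30 and 11.96 against 11.55 and 11.95. Untreated Trpm1 in both lines and Ripply3 in the wild-type line lay above parental replicate 2. These differences may thus reflect starting levels, which was not tested. In limma's test 0 of 13405 genes passed, the smallest adjusted p was 0.996, and 457 genes had an unadjusted p under 0.05, 285 higher and 172 lower. Without parental pair 2 the count was 1337, 992 higher and 345 lower, a fit in which the lone parental pair of the other RMA run was assumed to vary like the c-Myc pairs.

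In the same difference, the 23 ATF4 genes had a median of -0.48 and 2 were lower adjusted over the list alone, Atf3 and Ddit4 at -1.69 and -1.04 (camera adjusted p = 2.15e-08; adjusted p = 0.683 with an estimated correlation). Cholesterol synthesis had a median of 0.39, with Msmo1 at 0.85 and Insig1 at 0.56 (camera adjusted p = 1.82e-06; adjusted p = 0.683 with an estimated correlation). The germ cell list had a median of 0.31 and the p53 list of -0.37, each with camera adjusted p = 0.006 (adjusted p = 0.683 with an estimated correlation). Glycolysis had a median of 0.39 (camera adjusted p = 0.0196; adjusted p = 0.796 with an estimated correlation). Primitive endoderm and lysosome lists had medians of -0.17 and -0.19, each with camera adjusted p = 0.0449 (adjusted p = 0.683 with an estimated correlation). None of the members of these 6 further lists passed over all genes or adjusted over the list alone. The parental pairs themselves lay apart in these lists except primitive endoderm: ATF4 medians were -0.22 in replicate 1 and -1.32 in replicate 2, against -1.40 and -1.52 in the wild-type and T58A lines. Primitive endoderm medians were -0.057 and -0.004 in the replicates against -0.087 and -0.22 in the lines. Cholesterol synthesis medians were -0.12 and 0.51 in the replicates against 0.55 and 0.41 in the lines, and lysosome medians -0.05 and -0.61 against -0.65 and -0.43. Germ cell medians were -0.47 and -0.08 against -0.10 and -0.02, and p53 medians -0.23 and -0.80 against -0.60 and -0.72. The germ cell medians of both lines changed sign after centring and after quantile normalization, and that of replicate 1 became -0.324 and -0.301. For glycolysis the direction turned with the pair: the lines, at 1.18 and 1.05, lay above replicate 1 (-0.18) and below replicate 2 (1.39), which appears to share their RMA run.

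By day 2 of LY294002, averaged over parental, wild-type c-Myc and T58A c-Myc ESCs, LY294002 had raised and lowered genes as follows. Hs6st2 rose 9.71-fold (3.28 ± 0.22, n = 3 lines; adjusted p = 0.000385), Pim2 by 2.59, Dppa3, the maternal factor Stella, by 2.57, Lef1 by 2.54, Bnip3 by 2.39, Gadd45g by 2.35, Pou3f1, the gene for Oct6, by 2.32 and the protein kinase A subunit gene Prkar2b by 2.08. The Hedgehog inhibitor Hhip fell by 3.20, and so did Trpm1 (-3.15), the aspartic protease gene Napsa (-3.08) and Serpinb6c (-3.03). Niban1 (-2.66), the phosphatase gene Cdc14a (-2.60), B4galnt2 and Ripply3 (both -2.54) fell as well. Of 13421 genes 4099 passed, 2454 higher and 1645 lower, with 425 at least 2-fold and 4095 in the same direction in all 3 lines (smallest adjusted p = 9.69e-05).

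Of 19 naive genes at day 2, 12 fell, 1 rose and 6 did not pass over all genes, and 14 fell and 1 rose adjusted over the list alone. Tcl1 (-1.53), Tfcp2l1 (-0.85) and Fbxo15 (-0.99) fell, and Dppa3 was the member that rose (median -0.51, camera adjusted p = 1.37e-05; adjusted p = 0.614 with an estimated correlation). Of 13 formative genes 8 rose and 5 did not pass, and 9 rose adjusted over the list alone, among them Lef1, Dnmt3a by 1.67, Dnmt3b by 1.62 and Cdh2 by 0.88 (median 0.71, camera adjusted p = 9.52e-05; adjusted p = 0.614 with an estimated correlation). Of 19 glycolysis genes 12 rose and 1 fell over all genes, and 13 rose and 2 fell adjusted over the list alone, with Pkm up by 1.18, Pgk1 by 0.97 and Pfkl by 1.83 (median 0.74, camera adjusted p = 0.000576; adjusted p = 0.634 with an estimated correlation). Of 27 cholesterol synthesis genes 13 rose over all genes and 16 adjusted over the list alone, with Cyp51 up by 0.94, Acaca by 0.91 and Scd1 by 0.77 (median 0.31, camera adjusted p = 0.0047; adjusted p = 0.634 with an estimated correlation). In parental, wild-type and T58A ESCs the medians of single pairs were 0.41, 0.39 and 0.11 for cholesterol synthesis, 0.87, 0.96 and 0.42 for glycolysis and -0.78, -0.52 and -0.34 for naive genes.

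Of 23 ATF4 genes at day 2, 12 fell and 11 did not pass over all genes, and 16 fell adjusted over the list alone, with Atf5 down by a change of -1.90 and the serine synthesis genes Psph and Phgdh by -0.75 and -0.68 (median -0.63, camera adjusted p = 5.3e-06; adjusted p = 0.634 with an estimated correlation). Of 16 lysosome genes 9 fell over all genes and 11 adjusted over the list alone, with Hexa at -1.38, Sqstm1 at -0.91 and Ctsd at -0.96 (median -0.33, camera adjusted p = 1.43e-05; adjusted p = 0.614 with an estimated correlation). Of 17 p53 targets and CDK inhibitors 11 fell and 4 rose over all genes, the same numbers adjusted over the list alone, with Plk2 at -2.02, Mdm2 at -0.95, Pmaip1 at 1.11 and Cdkn2a at 0.80 (median -0.63, camera adjusted p = 0.000868; adjusted p = 0.616 with an estimated correlation). Of 13 heat shock and oxidative stress genes 6 fell and 1 rose over all genes and adjusted over the list alone, Dnajb1 and Hsph1 among those that fell (-0.54 and -0.69; median -0.33, camera adjusted p = 0.0071; adjusted p = 0.614 with an estimated correlation). Of 17 primitive endoderm genes 6 fell and 2 rose over all genes and adjusted over the list alone, with Apoe at -1.18, Sox7 at -1.26 and Lama1 at -1.41 (median -0.22, camera adjusted p = 0.0081; adjusted p = 0.614 with an estimated correlation). In parental, wild-type and T58A ESCs the day 2 medians of single pairs were -0.96, -0.75 and -0.06 for ATF4, -0.38, -0.49 and -0.18 for lysosome and -0.01, -0.19 and -0.46 for endoderm genes.

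Lists that did not pass at day 2 still held genes that did, where 4099 of all 13421 genes passed, 2454 higher and 1645 lower. At that rate most lists hold called genes, so these counts alone do not set a list apart. Of 24 FOXO and PI3K-feedback targets 8 rose and 3 fell (camera adjusted p = 0.3), with Pdk4, which restrains pyruvate oxidation, up by 1.23. Of 29 germ cell genes 7 rose and 4 fell (0.544), with Mael up by 1.72 and Dazl by 0.80. Of 24 replication genes 7 rose (0.3), among them Ccne1 by 0.68, and of 33 ribosome and Myc target genes 5 rose and 1 fell (0.544). Of 16 ERK response genes 4 rose and 1 fell (0.342), of 8 Wnt targets 2 rose and 1 fell (0.478), and of 16 Myc-Max network genes 3 rose and 3 fell (0.554), Mycn up by 1.70 and Mga at -0.64. Of 17 PI3K pathway genes 4 rose and 1 fell, Tsc1 (-0.80; 0.74), of 13 imprinted genes 3 rose and 3 fell (0.803), the paternally expressed Peg10 rising and Grb10 at -1.54, and of 7 DNA methylation genes 2 rose and 1 fell (0.74). Of 9 neuroectoderm genes 1 rose, Map2 (1.43), and 2 fell, Sox1 (-1.64) and Tubb3 (-0.31; 0.74), of 8 trophoblast genes 2 fell (0.459), and of 4 interferon genes 1 rose, Bst2 (1.43), and 1 fell (0.866). None of 7 primitive streak, 9 fibroblast and 1 2-cell-like genes passed (0.554, 0.866 and 0.653). Median and mean differed in sign for neuroectoderm (-0.03 and 0.02), fibroblast (-0.02 and 0.09), interferon (-0.06 and 0.21), DNA methylation (-0.06 and 0.36) and PI3K pathway lists (-0.03 and 0.05), with camera's direction down except for DNA methylation. The count of 4099 was 1010 without the wild-type line and 2663 without a line block.

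**Figure D2:**
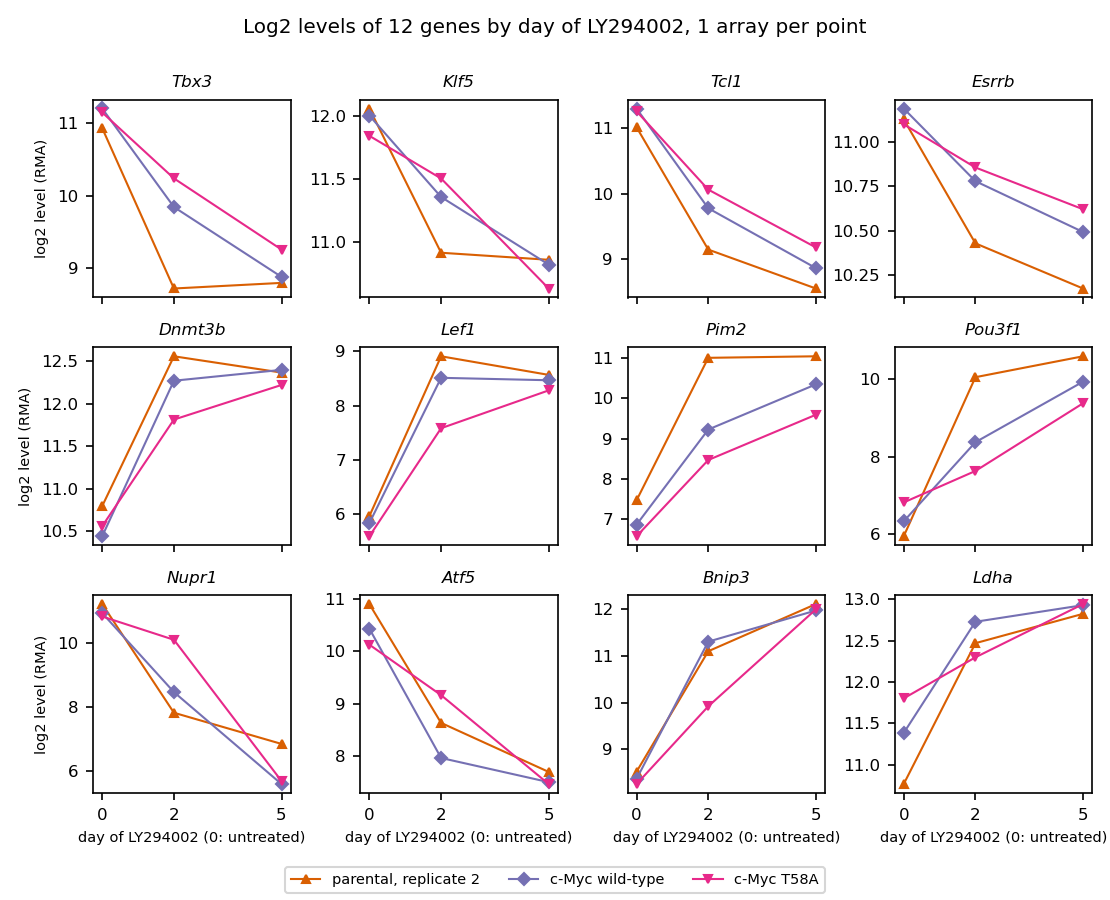
Log2 RMA level (vertical axes) of 12 genes against day of LY294002, with untreated as day 0, in parental replicate 2, wild-type c-Myc and T58A c-Myc ESCs (1 array per point). Pim2 went from 7.47 to 11.04 in parental ESCs and Tbx3 from 10.92 to 8.80 by day 5.

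At day 5 over the same 3 lines, a comparison added after the data were seen, Gbp2 had the largest rise and Nupr1 the largest fall among genes with 1 direction in all lines. The interferon-inducible GTPase genes Gbp2 and Gbp2b rose by 4.66 ± 0.76 and 4.19 ± 0.56 (n = 3 lines; adjusted p = 0.002 and 0.001). Fndc3c1 rose by 4.17, Slc40a1 by 4.15, Anxa3 by 3.68, Bnip3 by 3.64, Pou3f1 by 3.60 and Hs6st2 by 3.52. The stress-response gene Nupr1 fell by 4.94 and the water and glycerol channel gene Aqp3 fell by 3.88 (adjusted p = 7.66e-06). Napsa (-4.36), Hhip (-4.05), B4galnt2 (-3.83), G0s2, an inhibitor of lipolysis (-3.76), Trpm1 (-3.75) and Aldh1l2 (-3.61) fell as well. Of 13421 genes 5922 passed, 3444 higher and 2478 lower, and 940 changed at least 2-fold, with 5915 of all in the same direction in all 3 lines. Without the wild-type line the count was 2881. The list counts that follow stand beside 5922 of 13421 genes called in all, so called members alone do not set a list apart.

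All 23 ATF4 genes fell at day 5 over the 3 lines, over all genes and adjusted over the list alone, with Atf5 at -2.93, Vldlr at -2.65 and Psph at -1.42 (median -1.42, camera adjusted p = 2.78e-11; adjusted p = 0.533 with an estimated correlation). Of 19 naive genes 13 fell and 1 rose over all genes, and 13 fell and 2 rose adjusted over the list alone, with Tcl1 at -2.33 and Fbxo15 at -1.89 while Dppa3 rose by 3.52 (median -0.71, camera adjusted p = 2.62e-05; adjusted p = 0.533 with an estimated correlation). Of 13 formative genes 10 rose over all genes and 12 adjusted over the list alone (median 1.10, camera adjusted p = 7.21e-05; adjusted p = 0.533 with an estimated correlation). Of 19 glycolysis genes 13 rose and 1 fell over all genes, and 14 rose and 1 fell adjusted over the list alone, with Pfkl up by 2.54 and Pkm by 1.49 (median 1.23, camera adjusted p = 1.65e-05; adjusted p = 0.533 with an estimated correlation). Of 27 cholesterol synthesis genes 19 rose over all genes and adjusted over the list alone (median 0.46, camera adjusted p = 7.21e-05; adjusted p = 0.533 with an estimated correlation). Of 16 lysosome genes 12 fell over all genes and adjusted over the list alone (median -0.58, camera adjusted p = 1.57e-05; adjusted p = 0.533 with an estimated correlation). Of 17 p53 and CDK inhibitor genes 10 fell and 3 rose either way (median -0.71, camera adjusted p = 0.0175; adjusted p = 0.615 with an estimated correlation). Of 13 heat shock genes 6 fell and 2 rose over all genes, and 7 fell adjusted over the list alone, with Herpud1 at -2.26 and Nqo1 at -1.07 (median -0.27, camera adjusted p = 0.0321; adjusted p = 0.533 with an estimated correlation).

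In single pairs at day 5, 987 genes differed at least 2-fold in wild-type c-Myc ESCs, 547 higher and 440 lower, and 798 in T58A c-Myc ESCs, 400 higher and 398 lower. At day 2 the counts were 831 in parental, 529 in wild-type and 341 in T58A c-Myc ESCs, and Pou3f1 was higher by 4.10, 2.04 and 0.81 in that order. B4galnt2 differed by -3.32, -3.35 and -0.95. The day 5 changes of parental replicate 2 correlated over genes with those of the wild-type line at r = 0.874 and of the T58A line at 0.802, and the c-Myc lines with each other at 0.917. These differences between lines were not tested at day 2.

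In 2i, which blocks MEK and GSK3, LY294002 gave a smaller set of differences at day 5, from 1 pair and with no test. The highest genes were Id3 by 2.35, the feedback inhibitors of ERK signalling Spry4 by 2.17 and Dusp6, the gap junction gene Gja1 by 2.13, Map2 by 1.91 and Enox1 by 1.87. The lowest were Usp17la by -3.50, the Wnt target Sp5 by -2.93, Bhmt, which remethylates homocysteine, by -2.86, the meiotic gatekeeper Stra8 by -2.74, Ttn, and Alox12b by -2.38. In untreated 2i against serum, described below, Spry4, Dusp6, Gja1 and Enox1 were among the lowest and Bhmt among the highest. Both comparisons use the 1 untreated 2i array with opposite sign, so a deviation of that array would give such a mirror. Of 12633 genes 337 differed at least 2-fold, 55 higher and 282 lower. The formative list had a median of 0.44, above every random list, with Otx2 at 1.33, while the naive median was -0.09 at percentile 2.28. The germ cell list lay at -0.69 and glycolysis at -0.56, both below every random list, with Bnip3 at -1.59 and Sycp3 at -1.41. ATF4 genes had a median of -0.08 (percentile 4.39), p53 targets of -0.24 (percentile 0.06) and cholesterol synthesis of -0.20 (percentile 0.03). Hs6st2 and Slc40a1, among the largest rises in serum, differed by -0.09 and -0.54 in 2i. The 2i changes correlated over genes with those of parental replicate 1, apparently of the same RMA run, at r = 0.539 and with those of replicate 2 at 0.057.

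Untreated 2i ESCs were set against untreated parental serum replicate 1 of the same RMA run to show the effect of the medium. The lowest genes included Spry4 by -6.65, Dusp6 by -4.73 and Dusp4 by -4.59, which lie downstream of ERK, beside Zfp423 by -4.97, Gja1 by -4.33 and Enox1 by -4.28. Highest were Bhmt and Bhmt2 by 4.50 and 4.08, Trpm1 by 4.04, the transcription factor gene Spic by 3.89, Calcoco2 by 3.79 and Pdzrn3 by 3.75. The ERK list had a median of -0.87 with Myc at -3.25 and Egr1 at -2.74, the formative list -0.77 with Otx2 at -2.22, and the DNA methylation list -0.68 with Dnmt3l at -1.55, Dnmt3b at -1.46 and Dnmt3a at -1.44. Those 3 lists, neuroectoderm (-1.14) and DNA replication (-0.36) lay below every random list, and cholesterol synthesis (0.57) above every one. Scaling changed the size for neuroectoderm, to -0.52 after centring and -0.55 after quantile normalization, and for DNA methylation, to -0.38 and -0.37. Of 12581 genes 734 differed at least 2-fold, 384 higher and 350 lower. Against serum replicate 2, apparently of the other RMA run, the count was 2857, 996 higher and 1861 lower, with 524 genes shared.

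Untreated c-Myc lines were compared with untreated parental replicate 2 for differences that go with c-Myc overexpression before LY294002. Both lines were set against the same parental array, so its deviation enters both and their agreement is not replication. Other differences between the lines cannot be told apart from c-Myc. The 2 untreated parental samples differed at least 2-fold at 2083 genes, across the inferred RMA runs. Pttg1, the securin gene, was higher by 2.21 in wild-type and 2.28 in T58A c-Myc ESCs and Trpm1 by 1.37 and 1.73. The ascorbate transporter gene Slc23a1 lay at -2.49 and -2.98, and the calpain gene Capn3 at -1.83 and -2.57. The other largest differences in the wild-type line were Nell1 1.27, Ripply3 1.23, Mthfd2l 1.18, Cdkn2a 1.14, Pnma5 -2.30, Slc7a11 -1.87, Plet1 -1.86 and P2rx7 -1.84. In the T58A line they were Lefty2 1.63, Hpdl 1.63, Ntpcr and Mcrip2 (both higher), Lockd -2.54, Dpys -2.32, Slc27a2 -2.32 and Tmem156 -2.30. Ribosome biogenesis and Myc targets had medians of 0.11 and 0.23, at percentiles 99.5 and 100, and ATF4 genes of -0.30 and -0.34, below every random list. Members of a list can move together and random genes were drawn singly, so these places are no test. In all, 100 of 13023 genes differed at least 2-fold in the wild-type line, 13 higher and 87 lower, and 235 of 13163 in the T58A line, 43 higher and 192 lower. With quantile normalization the T58A split was 66 higher and 154 lower, or 30% higher against 18.3%.

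The last question was what ablation of Max by Dox does to ESCs with and without p110 alpha. In a fit over both lines that weights the Max-null line more, since it has 2 Dox samples against 1, 3 of the 5 higher genes with the smallest p-values were germ cell genes: Dazl, a germ cell RNA-binding protein, lay higher by 2.78 ± 0.33 (n = 3 Dox samples), the testis ADP/ATP carrier gene Slc25a31 by 2.77 and the kinase gene Stk31 by 1.90. Beside them stood Ubtfl1, a gene of early embryos, at 4.09 and the fibrinogen gene Fgg at 2.35. The Nodal antagonists Lefty2 and Lefty1 lay at -2.44 and -1.38, Myb at -1.49, Zic2 at -1.44 and Slc23a1 at -1.84. In limma's test 0 of 13535 genes passed, the smallest adjusted p was 0.561, and 701 had an unadjusted p under 0.05, 454 higher and 247 lower. Without the day 4 sample 56 genes passed, 53 higher and 3 lower, and without the day 6 sample 0. In the Max-null line alone, with both days against its 1 untreated sample, 1430 passed, 545 higher and 885 lower, where the spread is only that between days 4 and 6 and the deviation of the untreated sample is unmeasured.

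The germ cell list had the highest camera statistic of the Dox comparison. Of its 30 genes none passed over all genes and 16 rose adjusted over the list alone (median 1.38, camera adjusted p = 9.92e-21; adjusted p = 0.865 with an estimated correlation). All 3 2-cell-like genes tested, Tcstv1, Tcstv3 and Zfp352, rose adjusted over the list alone. Their median was 4.35 (camera adjusted p = 6.25e-05, and adjusted p = 0.865 with an estimated correlation, here 0.99). The list had been fixed with 11 genes, and the rest, Zscan4 genes among them, were not among the 18194 genes. The 24 ATF4 genes had a median of -0.90 with 0 passing either way (camera adjusted p = 7.41e-08; adjusted p = 0.865 with an estimated correlation). Primitive and visceral endoderm had a median of 0.51, trophoblast of 0.53 and primitive streak of 0.33, with 0 passing either way (camera adjusted p = 0.0013, 0.0259 and 0.034; each with adjusted p = 0.865 with an estimated correlation). Glycolysis had a median of -0.28 and ribosome biogenesis of -0.20, with 0 passing either way (camera adjusted p = 0.0442 and 0.0332; each with adjusted p = 0.865 with an estimated correlation).

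**Figure D3:**
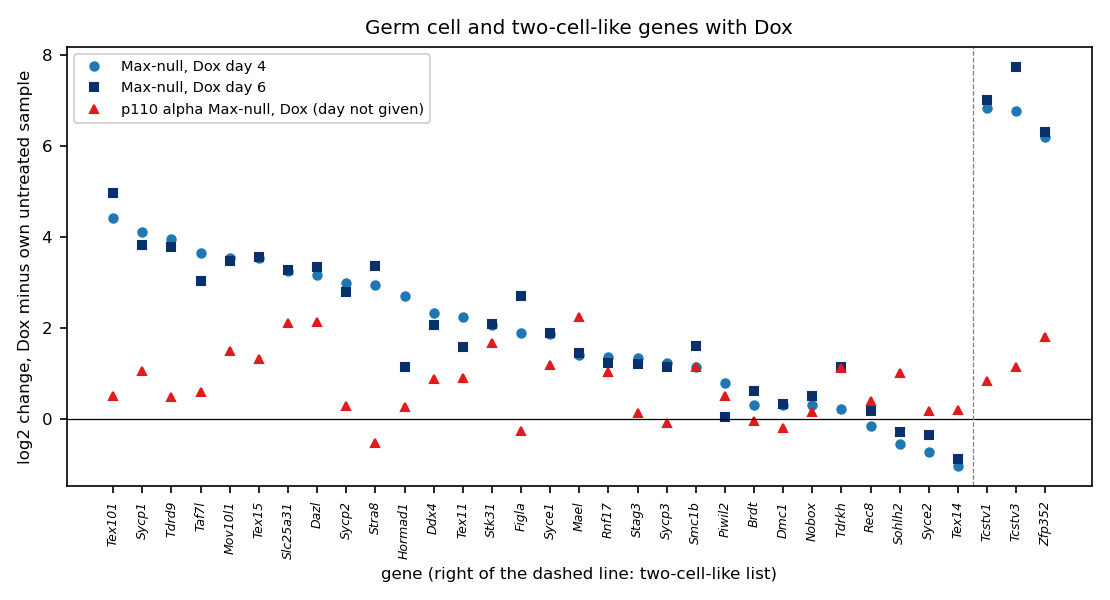
Log2 change with Dox against the own untreated sample (vertical axis) of the 30 germ cell and 3 2-cell-like genes tested, in Max-null ESCs at days 4 and 6 and in p110 alpha Max-null ESCs (1 array per point). Tex101 stood at 4.42, 4.97 and 0.52 and Mael at 1.41, 1.45 and 2.26 in these samples.

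In Max-null ESCs, from single samples and with no test, the highest genes with Dox were Pramel18 by 7.48 at day 4 and 8.11 at day 6, and the 2-cell-like genes Tcstv1 by 6.83 and 7.02, Tcstv3 by 6.78 and 7.74 and Zfp352 by 6.21 and 6.31. Spz1 was higher by 6.11 and 6.15 and Sp110 by 5.99 and 5.95. The lowest were Pdcl2 (-3.29 on both days), Mipol1 (-3.64 and -3.22), Sirt5 (-3.15 and -3.42), the fucosyltransferase gene Fut9 (-3.05 and -4.26), Lefty2 (-2.96 and -3.29) and Kdelr3 (-2.92 and -3.00). Of the germ cell list 21 of 30 genes were higher at least 2-fold at day 4 and 24 of 33 at day 6, with medians of 1.89 and 1.45, above every random list. The meiotic genes Sycp1 and Tdrd9 were higher by 4.11 and 3.97 at day 4. ATF4 genes had medians of -1.07 and -2.31, below every random list, with Nupr1 at -2.08 and -4.70, Trib3 at -2.16 and -4.40 and Chac1 at -2.44 and -4.08. Glycolysis had medians of -0.81 and -0.97, with Pgk1 at -1.05 and -1.07. Primitive endoderm genes had a median of 1.21 at day 6, above every random list, with Col4a2 higher by 2.11 and Sox17 by 1.72, while Pou5f1 differed by 0.07 and -0.38.

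Counts in Max-null ESCs were 1870 of 13457 genes at least 2-fold at day 4, 698 higher and 1172 lower, and 3435 of 14020 at day 6, 1249 higher and 2186 lower. With quantile normalization the day 4 split was 820 higher and 902 lower, or 47.6% higher against 37.3%. With each array centred on its median the day 6 split was 864 higher and 2839 lower, or 23.3% against 36.4%. The median change of all genes at day 6 was -0.087 as deposited, -0.288 after centring and 0.007 after quantile normalization, and the list medians named above kept their sign under all of these scalings. Beside these gene groups, the Gapdh control probe sets had a 3' minus 5' difference of 0.162 in untreated Max-null ESCs, 0.295 at day 4 and 0.412 at day 6, against 0.152 and 0.182 in p110 alpha Max-null ESCs without and with Dox.

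In p110 alpha Max-null ESCs 265 of 13261 genes differed at least 2-fold with Dox, 206 higher and 59 lower, on a day that the labels do not give. The highest were Ubtfl1 by 2.70, the homeobox gene Rhox5 by 2.54, the piRNA pathway gene Mael by 2.26, the glycogen phosphorylase gene Pygl by 2.25, Tgm2 by 2.21 and Ccser1 by 2.17. The lowest were Ror1 and Capn3 at -2.47, Dmrt1 at -1.88, Cdkn1c, the p57 inhibitor of cyclin-dependent kinases, at -1.86, Duox1 at -1.73 and Zic2 at -1.60. Pygl stood at -2.59 and Capn3 at 3.27 in Max-null ESCs at day 4. The germ cell median was 0.74, above every random list, with 12 of 28 genes at least 2-fold higher, Dazl by 2.14 and Slc25a31 by 2.12. The 2-cell-like genes Zfp352, Tcstv3 and Tcstv1 were higher by 1.82, 1.15 and 0.84. Their median went from 1.15 as deposited to 1.85 (centred) and 1.83 (quantile), so it depends on the scaling and on the members that pass the level filter. ATF4 genes had a median of -0.06 (percentile 2.88), glycolysis of 0.35 and cholesterol synthesis of 0.33 (percentile 100 for both). The Dox differences of this line correlated over genes with those of Max-null ESCs at r = -0.047 for day 4 and 0.006 for day 6. Whether the lines differ in their response was not tested.

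The untreated Max-null lines also differed from each other. In p110 alpha Max-null ESCs the cystine transporter gene Slc7a11 was higher by 3.03, Fbln5 by 2.79, G0s2 by 2.75, Atf5 by 2.50, Fst by 2.37 and Mir22hg by 2.34. The protease inhibitor gene A2m lay at -4.46, Pdcl2 at -3.95, Lefty2 at -3.85, Bnip3 at -3.81, the aldolase gene Aldoc at -3.76 and Fam183b at -3.47. Glycolysis had a median of -1.50, germ cell genes of -0.90 and cholesterol synthesis of -0.68, below every random list, and p53 targets of 1.04 and ATF4 genes of 0.81, above every one. In all 809 of 13212 genes differed at least 2-fold, 177 higher and 632 lower.

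As a yardstick for these counts, the 2 untreated parental samples in serum differed at least 2-fold at 2083 genes and the 2 day 5 samples at 1609, across the RMA runs. Untreated replicate 2 was higher at Zfp711 by 3.69, the imprinted RNA gene Rian by 3.44, Coch by 3.28, Hhip by 3.08, Neto2 by 3.06 and Zic2 by 3.04, and lower at A2m (-4.30), Pygl (-3.88), Pdgfrb (-3.60), Stra8 (-3.38), Tgm2 (-3.34) and Zc3h6 (-3.32). At day 5 replicate 2 was higher at Fndc3c1 by 4.32, Ltb by 4.23, Jun by 4.21, Samd4 by 3.97, Colec12 by 3.86 and Slc39a8 by 3.78, and lower at Vax2 (-2.35), F2 (-2.18), Tle5 (-2.02), Pdcl2 and Gdpd2 (both -1.91) and Chac1 (-1.85). The glycolysis list had a median of -1.44 between the untreated samples, below every random list. Such a place thus arose between 2 untreated samples of the same line. Between the day 5 samples the glycolysis median was 0.27 (percentile 50.1), where centring gave -0.072. The median of all genes was 0.202 and 0.28 as deposited, -0.136 and -0.078 after centring and -0.131 and -0.051 after quantile normalization. The share of genes higher in replicate 2 was 69.6% untreated (1450 of 2083) and 91.4% at day 5 (1470 of 1609) as deposited. It was 34.4% and 55.6% after centring, with 705 higher and 1343 lower and 641 higher and 511 lower, and 34.7% and 59.3% after quantile normalization, with 692 higher and 1303 lower and 671 higher and 460 lower.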

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

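Every test in this part was chosen after the result was seen, except the one of chance deviations over all genes of parental replicate 1. Glycolysis had a median Dox difference of 0.351 in p110 alpha Max-null ESCs and of -0.969 to -0.811 in Max-null ESCs, opposite directions that were not tested. For p53 targets and CDK inhibitors the medians were -0.253 in p110 alpha Max-null ESCs and 0.386 to 0.491 in Max-null ESCs, also not tested, and at day 6 scaling gave 0.221 (centred) and 0.66 (quantile). For Wnt targets they were -0.319 and 0.431 to 0.895, again not tested. The Gapdh control probe sets, outside the gene comparisons, had a 3' minus 5' difference of 0.295 at Dox day 4 and 0.412 at day 6 in Max-null ESCs, above the untreated range of -0.004 to 0.162. For the Actb control it was 0.875 in untreated Max-null ESCs, 1.105 at day 4 and 1.164 at day 6. The highest untreated Actb value was 0.987. With Dox, p110 alpha Max-null ESCs also lay above the untreated samples for both controls, at 0.182 (Gapdh) and 1.024 (Actb).

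With Dox, 1870 genes differed at least 2-fold at day 4 in Max-null ESCs and 265 in p110 alpha Max-null ESCs, a gap that normalization, RNA quality or unequal loss of Max might explain. Quantile normalization, which removes unequal spread of the arrays, left 1722 and 258 genes, a ratio of 6.67, which argues against normalization as the whole cause. At day 4, 214 genes were at least 4-fold higher and 95 at least 4-fold lower. These counts cannot decide on a loss of RNA ends for the rises, since normalized values are relative to the other probe sets. For the falls a loss of RNA ends stays open too, since the Gapdh 3' minus 5' difference moved by 0.134 at day 4, 0.25 at day 6 and 0.03 in the p110 alpha line. The Max probe set moved by -0.369 in the p110 alpha line and by -0.2 and 0.093 in Max-null ESCs, so unequal loss of Max is open too, as are the day of Dox and p110 alpha itself, which were not tested. Unequal starting levels are open as well, since the untreated lines, with 1 array each, differed at least 2-fold at 809 genes.

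The glycolysis list was higher with LY294002 at day 5 in parental replicate 2 and not in replicate 1. After quantile normalization over all arrays the pairs still differed by 1.63, with medians of -0.176 and 1.46, which argues against separate normalization as the whole cause. Between the untreated samples the median of replicate 2 minus replicate 1 was -1.62 and between the day 5 samples it was 0.085, so different starting levels may account for the gap. What made the untreated samples differ was not tested, and no biological explanation was tested.

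Fewer genes differed at least 2-fold with LY294002 at day 5 in the c-Myc lines, 987 and 798, than in parental replicate 2, 1340, mostly among higher genes (547 and 400 against 809), and day 2 had the same order (529 and 341 against 831). Both days of a line share its untreated array, so the day 2 order is not independent. The day 5 order held after quantile normalization, with 981, 793 and 1361, which argues against normalization as the whole cause. At the 469 genes that differed at least 2-fold in the separate parental replicate 1, 386 of them lower, the median change in that direction was 0.727 in parental replicate 2, 0.758 in the wild-type and 0.801 in the T58A line. For the lower genes alone it was 0.579, 0.646 and 0.678, so falls at these genes were not smaller in the c-Myc lines. These genes were picked in replicate 1 and not from the excess of falls in replicate 2. Chance deviations of the parental replicate 2 arrays may account for that excess, but its own genes were not tested. For the 83 higher genes the median change was 1.39, 1.49 and 1.41, but 1.55, 1.504 and 1.36 for the 89 higher genes of the 8-sample fit, so for the rises chance and an effect of c-Myc remain open.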

How the results depend on the processing

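The day 5 comparison over 3 lines and its alternatives were chosen after the data were seen, and the cause of a difference was not tested unless stated. Single genes were followed only where they were top genes of a comparison, by largest change or smallest p. None of these reversed its direction, but the majority direction of several counts turned. Genes named in a comparison only as list members were not followed there. Higher and lower genes became 705 and 1343 (centred) and 692 and 1303 (quantile) for the untreated replicates, and 996 and 1861 for 2i against serum replicate 2. They became 189 and 186 (centred), 932 and 883 (threshold of 0.1), 3139 and 2364 (without parental pair 1) and 3154 and 2373 (without parental pair 2) for c-Myc ESCs at day 5, and 2806 and 1905 for parental ESCs without pair 1. Near-even splits turned for T58A at day 2 (204 and 148 centred, 799 and 583 at 1.5-fold) and at day 5 (358 and 363 at the 60th percentile, 261 and 274 with the mean of the probe sets), and for wild-type at day 2 (900 and 887 at 1.5-fold). Of the values of single named genes under the alternatives, 1690 stayed the same, 128 lost the call, 24 gained it and 98 moved. Calls were lost or gained only in the tested comparisons, where the same means that direction and side of the threshold were kept. All values that moved came from untested pairs. These pairs have no call, so there the same means only that a value was not counted as moved. Under other level filters, scalings, probe sets and priors the count stayed between 56 and 87 in parental ESCs and between 3810 and 4504 at day 2, and at 0 for the difference and for Dox. Single pairs carry no test, and genes near background are limited by signal.

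At a threshold of 0.1 LY294002 at day 5 gave 455 genes in parental and 1815 in c-Myc ESCs. In the c-Myc lines it gave 533 with the level filter at the 60th percentile and 536 with a trended, robust prior. The pair as a block mattered: without it the counts were 0 in parental ESCs, 44 in the c-Myc lines and, at day 2 without the line block, 2663. The fit without a pair block crosses the inferred RMA runs, and whether that lowered the counts was not tested. In the parental samples alone the count was 0 with the block and 0 without it.

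Leaving out 1 pair, line or day gave 0 to 4711 genes in parental ESCs, 0 to 5527 in the c-Myc lines, and 0 to 1337 for their difference. It gave 1010 to 3119 at day 2, 2881 to 4914 at day 5 over 3 lines and 0 to 56 for Dox. At day 5 the count was 4711 in parental ESCs without parental pair 1, and 5527 in the c-Myc lines and 1337 for the difference without parental pair 2. It was 0 in parental ESCs and in the c-Myc lines without the wild-type or without the T58A line. The lowest at day 2 (1010) and day 5 (2881) came without the wild-type line, and 56 without Dox day 4. A lone sample was then assumed to vary like the others. Max-null ESCs alone gave 1430, with the spread taken from days 4 and 6 alone. With an estimated correlation 0 lists passed in each of the 6 comparisons, against 7, 8, 7, 9, 8 and 8. That setting also rests on the few residual degrees of freedom of each fit. The ERK list in parental ESCs had an estimated correlation of -0.0437, below the preset 0.01. Its camera adjusted p still went from 0.0307 to 0.777. These counts of 0 thus do not show that correlated genes removed the results.

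At 1.5-fold, which admits more genes by construction, LY294002 at day 5 gave 1471 and 3380 genes in the parental pairs, 2715 and 2295 in the wild-type and T58A lines and 1099 in 2i. At day 2 it gave 2466, 1787 and 1382 in parental, wild-type and T58A ESCs. Dox gave 4564 and 6961 in Max-null and 1120 in p110 alpha Max-null ESCs. Untreated samples gave 1986 for 2i, 590 and 1336 for the c-Myc lines, 2648 for p110 alpha and 5128 for the replicates, which had 4436 at day 5. With the mean of the probe sets, untreated wild-type c-Myc ESCs gave 64 and day 2 gave 345 in the wild-type and 227 in the T58A line. Against serum replicate 2, of the other RMA run, 2i gave 2857.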

Other observations

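The test of c-Myc against the LY294002 change was chosen after the result was seen. In Max-null ESCs further genes differed with Dox, from single samples with no test. The heat shock genes Hspa1a and Hspa1b were higher by 4.27 and 3.23 at day 4 and by 4.58 and 3.34 at day 6, although their list had medians of 0.20 and -0.10 on these days, the latter 0.187 after quantile normalization, and did not pass in the Dox test (camera adjusted p = 0.831). The keratin genes Krt8 and Krt18 were higher by 2.85 and 2.95 at day 6, and trophoblast genes had a median of 0.95, with 5 of 10 at least 2-fold higher. Imprinted genes had a median of 0.57 at day 4 and did not pass in the Dox test (camera adjusted p = 0.331), and the growth factor gene Igf2 was higher by 1.53 at day 4 and 2.66 at day 6. The CDK inhibitor gene Cdkn1b lay at -1.81 and -3.10.

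In p110 alpha Max-null ESCs with Dox, formative and primed epiblast genes had a median of -0.18 (percentile 0.38), against 0.79 at day 4 and 0.53 at day 6 in Max-null ESCs. Lysosome and autophagy genes had a median of -0.22 in this line, at percentile 0.04. In untreated T58A c-Myc ESCs the glycolysis list had a median of 0.30, above every random list, and FOXO and PI3K-feedback targets one of -0.28, at percentile 0.03.

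The 3 untreated and 3 treated samples of the same lines make 10 splits, too few for a share under 0.05. At day 2 the real split gave 4099 genes and the highest other 0. At day 5 the real split gave 5922 and the highest other 0. On each day 1 split gave as many, the real one. The other splits mix treated with untreated samples and do not all part the pairs, so the treatment effect enters their spread and their counts of 0 say nothing about chance.

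A hypothesis that c-Myc overexpression moves untreated ESCs in the direction of the LY294002 change was tested over genes against the separate parental pair. The r was 0.125 for the wild-type and 0.135 for the T58A line, where genes are not independent replicates. That pair appears to belong to the other RMA run. The day 5 change of parental replicate 2 itself reached only r = 0.428 with it. A low r with this pair therefore cannot exclude the hypothesis. A second hypothesis was that LY294002 and loss of Max change the same genes in the same direction. The r of Dox day 4 was -0.044 with parental replicate 2 and 0.164 with replicate 1, which leaves it undecided.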
